A study of Mus musculus with 15 samples.

How the data were processed

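The series holds 15 samples in 5 groups of mouse material. HITS-CLIP of Mbnl3 was done on WT forelimb, Mbnl3 ΔE2 forelimb and C2C12 cells, and RNA-seq on WT and ΔE2 forelimb, with 3 samples each. Per the labels, each forelimb CLIP replicate held 4 forelimbs of 2 embryos at day 15, each C2C12 replicate 5 plates grown in 20% serum, and RNase A was used at 55 and 0.55 U/ml. Lysates were denatured in 1% SDS and diluted to 0.1% before 5 µg of antibody was added, per the labels' protocols. The replicates are labelled as biological. The p-values of the exon table come from group totals and hold no spread between replicates.

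CLIP tags were aligned to mm9 with Novoalign, per the submitters' processing notes; the version of Novoalign is not given in the sources used here. The deposited CLIP files list 1 tag per line with its strand, and carry a score per tag whose meaning is not stated, so that the score column of the authors was not used. Within each deposited forelimb file, no pair of tags shared position, strand and a 5-base barcode, and the number of reads behind each tag stands with it. Tag counts were made here from the deposited lines. Reads behind the forelimb libraries numbered from 2538099 to 25298063, and reads per tag ran from 61.8 to 428. The C2C12 file is the authors' combination of the libraries, without a replicate label, and holds repeated molecules, which were counted once here.

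RNA-seq reads were aligned to mm9 with TopHat 1.3.2 and Bowtie, per the submitters' processing notes. The deposited table of cassette exons gives estimated counts of tags per isoform, as 1 total per group that is not a whole number, per the file headers and values. It also gives an odds ratio of the isoforms between the groups, per the file headers. Its p-value per event is from Fisher's exact test, with an adjusted p-value, per the file headers. The change in inclusion was recomputed from the deposited estimated counts for 98 of 98 events within a tolerance of 0.0005. Fisher p-values from these counts, rounded to whole numbers, matched for 98 of 98 events within a looser tolerance on the log scale. A header of the deposited table names another muscleblind gene for the mutant, so its column is called the knockout column here. All 84 gene IDs matched the symbol table used here, and 7 had a newer symbol. Reference coordinates were not used, since that table is of another build (GRCm38.p6), and no gene is named for a CLIP cluster outside the events.

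Tags of the forelimb libraries that overlapped by at least 1 nt on the same strand were merged into 191766 clusters. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10, quasi-likelihood test, Benjamini-Hochberg adjusted p at or under 0.05). The common dispersion was 0.0435 with 3 residual degrees of freedom. CPM values are counts scaled to 1000000 tags, for clusters over the tags in tested clusters after TMM scaling, and for events over all tags of the library. Clusters compared between forelimb and C2C12 were scaled over all tags of the set. Library size as an alternative scaling means the tags in tested clusters. DESeq2 1.42.0 was an alternative. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest. The procedure was tested on simulated counts for this comparison of 3 against 2 libraries, with 200 of 290 clusters changed: it recovered 41% of clusters changed 2-fold and 84% of those changed 4-fold, and 4 of 129 calls were false. The simulated libraries were independent and shared no molecules, and most clusters were changed, which left few that could be called falsely. The share of false calls therefore does not carry over to the data.

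Departures from the plan made before the data were examined are these. The plan collapsed tags by position, since no molecular barcode was described; the files hold one, so barcoded tags were counted and collapse by position became an alternative. The plan compared 3 with 3 libraries; ΔE2 replicates 2 and 3 were counted as 1 library, and the 6 libraries as labelled became an alternative. Tests per gene, tests of gene lists on CLIP counts, and the motif count need an mm9 annotation or genome and were not analysed here. For the same reason, tags from ribosomal, transfer and small nucleolar RNA, planned as classes of their own, were not set apart. Of the 16 gene lists, only their members in the table of exons are reported.

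Named clusters are the 10 with the largest fold in each direction among those past the threshold whose values did not overlap between the genotypes. For binding, the rule took the 15 clusters with the most tags in each set, of which a part is described. For the exon table, the rule took the 10 largest changes in each direction, with Mbnl1 always named. Clusters that share a locus within 10000 nt, and Fgfr2, Arhgef12 and Psme3, were singled out after their values were seen.

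A WT cluster was reproducible with at least 10 tags in all and at least 1 in each of 3 libraries, and a ΔE2 cluster with at least 1 in both libraries. Expected overlap came from 100 shuffles, and thinned values are means of 20 draws. Shares of tags were compared with two-sided exact permutation tests over 10 splits and adjusted over the 4 classes. Intervals are 95% Wilson intervals and cover counting error only. Replicate numbers are not stated to mark a shared litter or day.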

Results

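Binding of the muscleblind protein Mbnl3 to RNA was measured by HITS-CLIP, in which RNA is crosslinked to protein by ultraviolet light, precipitated with an antibody and sequenced as short tags. Muscleblind proteins bind RNA and regulate alternative splicing. The tissue was the forelimb of mouse embryos at day 15, from wild-type (WT) animals and from animals homozygous for the Mbnl3 ΔE2 allele, with 3 libraries per genotype. Mbnl3 HITS-CLIP was also done on C2C12 cells, a mouse myoblast line, from which 3 libraries were combined by the authors. RNA-seq of 3 WT and 3 mutant forelimbs was given as the authors' table of changed cassette exons. The WT libraries held 35413, 74123 and 124309 tags, and the ΔE2 libraries 67279, 40531 and 59115 tags. The combined C2C12 set held 677787 tags, or 550124 after tags with the same position and barcode were counted once. ΔE2 replicates 2 and 3 shared 33916 molecules of the same position and barcode, 83.7% and 57.4% of their tags, with 99.9% and 99.8% of their reads. Reads per shared molecule correlated at 0.977 on the log scale, across molecules. Their cluster counts gave a chi-square per degree of freedom of 0.571, which shared molecules lower by construction, and 1.24 over 28 clusters without them (p = 0.180). They were counted as 1 library of 65730 tags, which left 3 WT and 2 ΔE2 libraries. WT replicates 2 and 3 shared 32.4% and 19.3% of their tags, with 80.9% and 50.1% of their reads, but reads per shared molecule correlated at -0.297. Their chi-square per degree of freedom was 0.850 with all molecules and 1.2 over 285 clusters without shared ones (p = 0.0109). They were kept apart, a choice on which the calls below depend. All coordinates are of the mm9 build, counted from 1. Tags at the Mbnl3 gene were not analysed here, because no mm9 annotation was used.

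The comparison of ΔE2 with WT forelimbs asked at which sites more or less RNA was recovered from forelimbs labelled ΔE2. The libraries' deposited designations carry the number 37 for WT and C2C12 and 27 for ΔE2, which no label explains, so a difference between the sets other than genotype is not ruled out. The titles of the ΔE2 CLIP samples read Mbnl3 KO, and whether their tags came from RNA bound by Mbnl3 was not tested. Tags gathered in 62 clusters that differed between the genotypes, of which 44 were higher and 18 lower in ΔE2. Values are in CPM, the count of a cluster scaled to 1000000 tags in tested clusters after TMM scaling. The highest fold was at a 54-nt cluster on the plus strand of chromosome X, 23585757 to 23585810, at 477 ± 121 CPM in WT (SD, n = 3) and 5543 ± 3187 in ΔE2 (SD, n = 2). Its tags numbered 2, 6 and 7 in the WT libraries and 23 and 43 in the ΔE2 libraries. Its log2 fold was 3.44 with a standard error of 0.47 (edgeR adjusted p = 0.00316). The deepest loss was at the minus strand of chromosome 8, 87228858 to 87228956, with 1906 ± 789 CPM in WT (SD, n = 3) and 162 ± 27.1 in ΔE2 (SD, n = 2). These came from 15, 13 and 25 tags in WT and 1 in each ΔE2 library, so the ΔE2 SD reflects scaling alone. There the log2 fold was -3.35 with a standard error of 0.71 (edgeR adjusted p = 0.0134).

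Several gains lay close together. The clusters were not assigned to genes or RNA classes, so gains on ribosomal RNA were not set apart. On the minus strand of chromosome 19, between 5796081 and 5799561, 5 of the 6 tested clusters rose in ΔE2. The sixth, from 5797382 to 5797951, had the most tags and was not called, at 20416 ± 1897 CPM in WT (SD, n = 3) and a mean of 21390 in ΔE2, a log2 fold of 0.06 with a standard error of 0.28. The cluster from 5798304 to 5798584 went from 3085 ± 1053 CPM in WT (SD, n = 3) to 15724 ± 1609 in ΔE2 (SD, n = 2), a log2 fold of 2.27 (edgeR adjusted p = 0.00316), or 1.49 with tags collapsed by 5′ end. Its neighbours from 5799127 to 5799244 and from 5799447 to 5799561 had log2 folds of 2.57 and 2.16. On the plus strand of chromosome 17, between 39980534 and 39984215, 4 of the 6 tested clusters rose, with log2 folds from 1.07 to 1.80, and the others had 0.83 and 1.04. On the minus strand of chromosome 7, between 149761614 and 149762584, 3 of the 4 tested clusters rose, with log2 folds from 1.08 to 1.72, and the other had 0.62. On the plus strand of the mitochondrial chromosome, between 1094 and 2677, both of the 2 tested clusters rose, with log2 folds of 1.09 and 1.73. With library size in place of TMM scaling, both mitochondrial calls ended (edgeR adjusted p = 0.146 and 0.0668), as did 1 call at each of the loci on chromosomes 19, 17 and 7. Library size here is the number of tags in tested clusters, not in the whole library.

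The other named gains, among the 10 with the largest fold, stood alone. On the plus strand they lay on chromosome 5 from 108536484 to 108536552 (log2 fold 3.22) and from 115940316 to 115940379 (2.62). Further plus-strand gains lay on chromosome 6 from 3151264 to 3151358 (2.81), chromosome 17 from 24665426 to 24665498 (2.14) and chromosome 12 from 70411337 to 70411423 (2.11). The cluster on the minus strand of chromosome 10 from 41901649 to 41901803 rose by 2.29 on the log2 scale. The chromosome 6 cluster had 2395 ± 200.1 CPM in WT (SD, n = 3) and 16762 ± 11166 in ΔE2 (SD, n = 2), and its log2 fold fell to 1.54 with tags collapsed by position and 1.36 by 5′ end.

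The clusters that fell mostly stood alone. On the plus strand, log2 folds were -2.40 on chromosome 11 from 109528893 to 109529012, -2.29 on chromosome 9 from 43143209 to 43143462, and -1.79 on chromosome 7 from 148276138 to 148276359. On the minus strand, they were -2.20 on chromosome 1 from 92672542 to 92672772, -2.02 on chromosome 3 from 36348108 to 36348256, and -1.94 on chromosome 7 from 149841597 to 149841713. Further minus-strand losses were on chromosome 9 from 42772589 to 42772818 (-1.94), chromosome 11 from 102151933 to 102152112 (-1.81) and chromosome 15 from 79658018 to 79658122 (-1.73). The chromosome 9 plus-strand cluster fell from 5122 ± 744 CPM (SD, n = 3) to 949 ± 1085 (SD, n = 2), from 12 and 1 tags in the ΔE2 libraries. Without ΔE2 replicate 1 its log2 fold was -4.58, and that of the minus-strand cluster on chromosome 9 was -3.88. With each shared molecule given to the library with most of its reads, log2 folds were -3.93 for the chromosome 9 plus-strand cluster, -3.62 for chromosome 11 at 109528893, -3.89 for chromosome 3 and -2.90 for chromosome 15. The loss on chromosome 7 at 149841597 was called in edgeR without WT replicate 1, but not without any other library (adjusted p from 0.0521 to 0.158), and 8 of its 12 values under alternatives missed the threshold. So did 9 of 19 for chromosome 11 at 102151933, 8 of 19 for chromosome 15 and 8 of 20 for chromosome 7 at 148276138, in 4, 3 and 3 of the 6 fits without 1 library. Only 2 clusters on chromosome 5, both between 93602358 and 93603002 on the plus strand, fell within the same 10000 nt.

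The test was run on 276 of 191766 clusters, those past the low-count filter. Values did not overlap between genotypes at 154 of the 276 clusters, where chance gives 20% for a single cluster, and at all 62 that were called. The clusters share the same 5 libraries and are not independent, and the test favours clusters without overlap. These counts are therefore a description only. Of the 20 named clusters, 13 lost their edgeR call without some library: 10 without WT replicate 2, 6 without WT replicate 3, and 8, 2 and 1 without ΔE2 replicates 1, 2 and 3 (adjusted p from 0.0508 to 0.213). With library size in place of TMM scaling, 74 clusters were called, 28 higher and 46 lower in ΔE2, so the balance of gains and losses depended on the scaling. That size counts tags in tested clusters only, 10.6% to 14.8% of the tags of each library. The count was 7 with DESeq2 (7 higher, 0 lower in ΔE2) and 35 with DESeq2 on the filtered clusters (31 higher, 4 lower). Without the filter it was 19 (11 higher, 8 lower), of which 8 were among the 62. With tags collapsed by 5′ end it was 41 (31 higher, 10 lower). It was 16 without WT replicate 2 (14 higher, 2 lower) and 22 without WT replicate 3 (17 higher, 5 lower). The count was 0 in edgeR with WT replicates 2 and 3 counted as 1, where 72 of 238 had an unadjusted p under 0.05. In that fit all 58 of the called clusters that could be tested kept their sign, with a median absolute log2 fold of 1.68 against 1.72 for the 62.

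**Figure D1:**
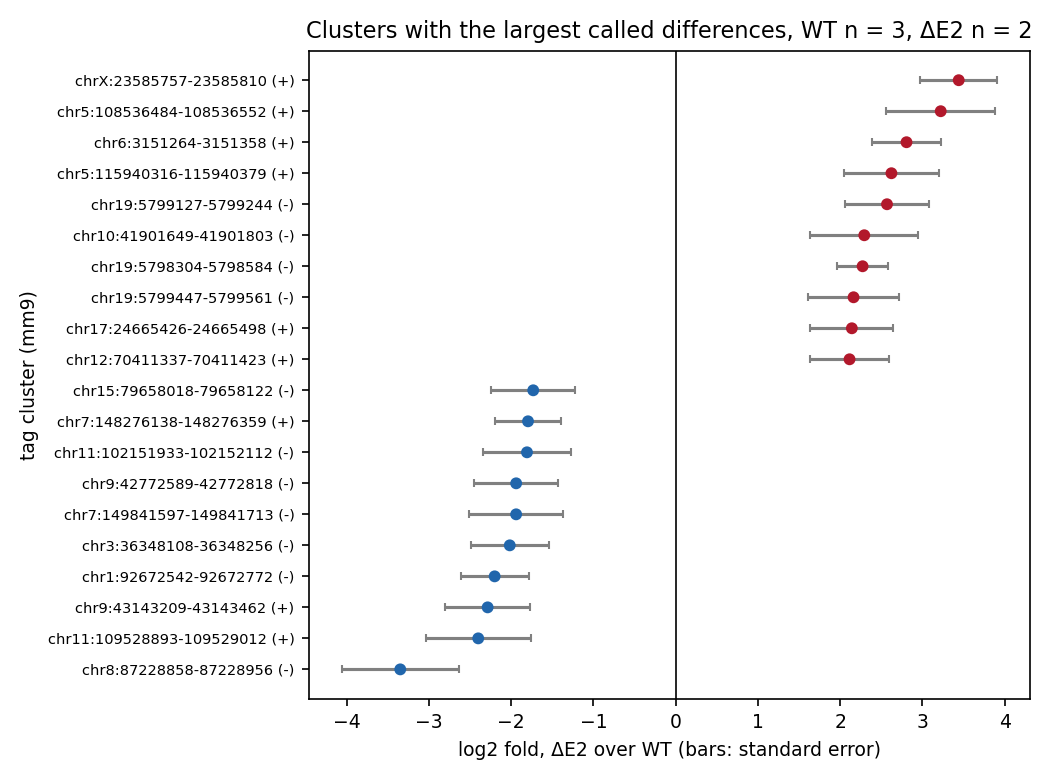
Log2 fold of tag counts, ΔE2 over WT forelimb, on the x axis for the 10 clusters with the largest called gain (red) and the 10 with the largest called loss (blue), by mm9 position on the y axis. Points are edgeR estimates and bars their standard errors; the points run from -3.35 on chromosome 8 to 3.44 on chromosome X.

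The share of tags from each part of the genome was compared to see whether the genotypes differed in broad classes. Mitochondrial RNA gave 0.0799% ± 0.0115 of tags in WT (SD, n = 3) and 0.135% ± 0.00966 in ΔE2 (SD, n = 2). Both ΔE2 libraries lay above the 3 WT libraries (two-sided exact permutation p = 0.1, adjusted 0.2), and 0.1 was the smallest p that 10 splits allow. The plus strand gave 49.3% ± 0.198 of tags in WT (SD, n = 3) and 50.4% ± 0.773 in ΔE2 (SD, n = 2), with an exact permutation p of 0.1. The X chromosome gave 2.82% ± 0.151 in WT (SD, n = 3) and 3.00% ± 0.0760 in ΔE2 (SD, n = 2), with an exact permutation p of 0.2. Autosomes gave 97.1% ± 0.134 in WT (SD, n = 3) and 96.8% ± 0.0998 in ΔE2 (SD, n = 2), also with an exact permutation p of 0.2. No class passed a threshold of 0.05, which this design cannot reach. The plus-strand difference was 1.10 percentage points, or 0.626 with tags collapsed by position, and the X-chromosome difference was 0.181, or 0.0941 without WT replicate 1. In C2C12 cells, mitochondrial RNA gave 0.327% of tags (95% Wilson interval 0.312 to 0.342), the X chromosome 3.14% and the plus strand 48.0%. C2C12 tags were 26 to 30 nt long and forelimb tags 19 to 38 nt, so comparisons with C2C12 also hold a difference in tag length.

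**Figure D2:**
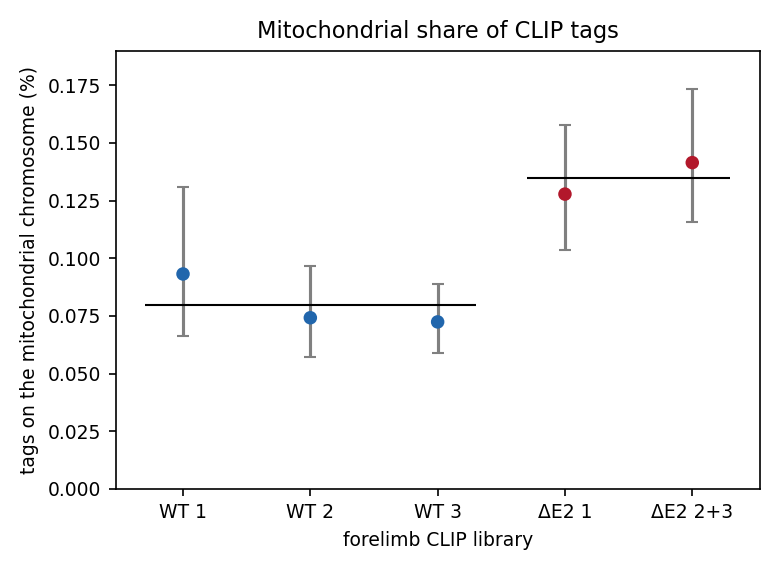
Percent of tags on the mitochondrial chromosome (y axis) in each forelimb CLIP library (x axis), with WT in blue and ΔE2 in red. Bars are 95% Wilson intervals, which cover counting error only, and lines are group means of 0.0799% and 0.135%.

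Sites with tags were then compared between forelimb and myoblasts. Here too, tags from ribosomal RNA were not set apart. The densest WT forelimb cluster lay on the plus strand of chromosome 17 from 39984118 to 39984215, with 950 tags or 0.406% of WT tags, and its neighbour from 39984605 to 39985113 had 919. The same stretch held the densest C2C12 cluster, from 39984368 to 39985249, with 1540 tags. The minus strand of chromosome 19 was bound in both. From 5797601 to 5797951, WT had 559 tags and C2C12 180, or 2390 and 327 per 1000000 of all tags in the set. This scaling differs from the CPM of the tested clusters above, so the values cannot be set side by side. Over the wider C2C12 cluster, from 5797155 to 5799352, WT had 919 tags and C2C12 683, or 3930 and 1242 per 1000000 of all tags. A cluster on the minus strand of chromosome 7 from 149844614 to 149845160 had 755 WT, 207 ΔE2 and 0 C2C12 tags. In C2C12, 0 tags allow up to 5.45 per 1000000 of all tags (3 counts, counting error only). Likewise, 3 clusters on the minus strand of chromosome 15, at 101676124, 101689208 and 101748980, had 394, 367 and 324 WT tags and 0 in C2C12. The same held at chromosome 11 from 99250054 to 99250673 on the minus strand with 440 WT tags, and on the plus strand at chromosome 12 from 110698609 to 110698810 with 426 and chromosome 10 from 18576304 to 18576674 with 307. Chromosome 11 from 94814069 to 94814264 had 475 WT tags and 7 in C2C12. The reverse held on the plus strand of chromosome 5 from 104869255 to 104870062, with 242 tags in C2C12, 3 in WT and 1 in ΔE2 forelimbs. RNA amounts in C2C12 were not measured in this series. A lack of tags can therefore mean a lack of the RNA rather than a lack of binding.

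Reproducible clusters numbered 1379 in WT forelimb and 463 in ΔE2 forelimb, and 2015 clusters passed the minimum of 10 tags in C2C12. The WT clusters numbered 530 without WT replicate 3 and 839 without WT replicate 2, and the ΔE2 clusters 184 without ΔE2 replicate 1. With unshared molecules they numbered 632 and 309. Of the WT clusters, 26.4% were also found in ΔE2 (95% Wilson interval 24.1 to 28.8) and 33.8% in C2C12 (31.3 to 36.3). Shuffled clusters gave 0.458% and 2.45%. Of the ΔE2 clusters, 80.1% were found in WT and 40.0% in C2C12 (95% Wilson interval 35.6 to 44.5). By place, 168 WT clusters were found in both other sets, 196 in ΔE2 alone, 298 in C2C12 alone and 717 in neither. The order of these shares changed with depth. With each set thinned to 133009 tags, 46.8% of WT clusters were found in ΔE2 and 10.7% in C2C12, and 12.7% of ΔE2 clusters in C2C12. The share of WT clusters found in ΔE2 was 50.6% without WT replicate 3 and 10.7% without ΔE2 replicate 1.

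**Figure D3:**
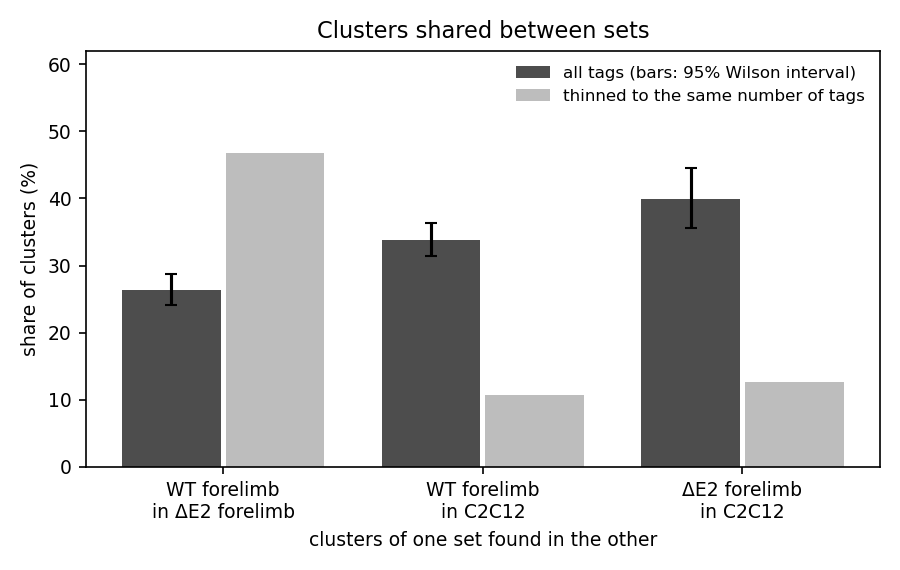
Share of clusters of the first set found in the second set (y axis, percent) for 3 pairs of sets (x axis), with all tags in dark grey and with sets thinned to 133009 tags in light grey. Error bars are 95% Wilson intervals; thinning raised the WT to ΔE2 share from 26.4% to 46.8% and lowered the WT to C2C12 share from 33.8% to 10.7%.

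The RNA-seq comparison asked which cassette exons changed inclusion in mutant forelimbs. The authors' deposited table listed 98 events in 84 genes, of which 53 had higher and 45 lower inclusion in its knockout column. In the authors' deposited table, the widest gain was a 54-nt exon of Clta, the clathrin light chain, within chromosome 4 from 44038321 to 44044306, with inclusion of 0.673% in WT and 90.0% in the knockout (adjusted p = 3.39e-50). The authors' deposited table also gave the widest loss to Clta, for a 36-nt exon within 44043087 to 44045725, from 96.5% to 25.8% (adjusted p = 1.37e-12). These events share a junction in the authors' deposited table, with 0 tags in WT and 32.1 in the knockout. Other gains in the authors' deposited table were Adamts6, a metalloprotease (10.3% to 53.7%), Trim26 (26.9% to 66.2%), Slc9a5, a sodium-proton exchanger (18.2% to 56.3%) and Top3b, a topoisomerase (22.2% to 53.4% in its most changed event). The authors' deposited table listed 5730419I09Rik, now named C2cd5, at 41.3% in WT and 70% in the knockout. The authors' deposited table put Psme3, a proteasome activator subunit, at 0.187% in WT and 22.6% in the knockout, with the smallest adjusted p of 1.98e-51. Among its other losses, the authors' deposited table had Ube2d3, a ubiquitin-conjugating enzyme (61.0% to 26.1%), Cobl, an actin nucleator (59.9% to 27.2%), Zfp322a (84.0% to 54.0%) and Dysf, the muscle membrane repair protein dysferlin (37.5% to 9.50%). Cuedc2 (64.3% to 36.4%), 2210018M11Rik, now named Emsy (60.9% to 33.4%), and Lsm6 (42.9% to 18.7%) also fell in the authors' deposited table. Cux1, a transcription factor, went from 83.3% to 56.5% and Rbm10, an RNA-binding protein, from 96.2% to 70.4% in the authors' deposited table.

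Gene lists fixed before the data were examined had few members among these events. In the authors' deposited table, 3 cartilage genes had 4 events, all with higher inclusion in the knockout, of which a pair are forms of 1 Col2a1 exon. Values in the authors' deposited table were 5.88% to 35.1% for Col11a2, a fibrillar collagen of cartilage, 15.3% to 28.0% for Acan, the cartilage proteoglycan aggrecan, and 52.8% to 67.8% for the wider of the Col2a1 changes, in the main cartilage collagen. Of muscleblind and splicing regulators, the authors' deposited table had a 223-nt exon of Mbnl1 (48.3% to 63.7%, adjusted p = 0.0396) and a pair of Rbm9 exons, now named Rbfox2, of which a 40-nt exon rose (63.8% to 76.7%) and a 43-nt exon fell (54.0% to 34.3%). The tags that skip the 40-nt exon, 73.4 in WT and 70.8 in the knockout, are in the authors' deposited table also those of an inclusion junction of the 43-nt exon, so the Rbm9 changes are not separate measurements. Cdk2, of the cell cycle list, had higher inclusion in the authors' deposited table. The other 13 lists, muscle contractile genes and myogenic regulators among them, had 0 members in the authors' deposited table. The 98 events of the authors' deposited table held 87 distinct exons with overlapping forms counted once, of which 53 had a length that was a multiple of 3, and lengths ran from 16 to 759 nt. The authors' deposited table listed group totals, so the spread between replicates was not open to a test, and in 25 events, among them the 54-nt Clta exon, Mbnl1, Top3b, Lsm6, Fgfr2 and the 40-nt Rbm9 exon, the tags on the inclusion junctions, summed over WT and knockout, differed by more than 4-fold. In WT or knockout taken alone, 29 events of the authors' deposited table did so, among them Psme3, 5730419I09Rik and the 36-nt Clta exon, with 0 and 49.8 tags on its junctions in WT. At a change of at least 0.2 in inclusion, 32 events remained in the authors' deposited table, 17 higher and 15 lower.

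**Figure D4:**
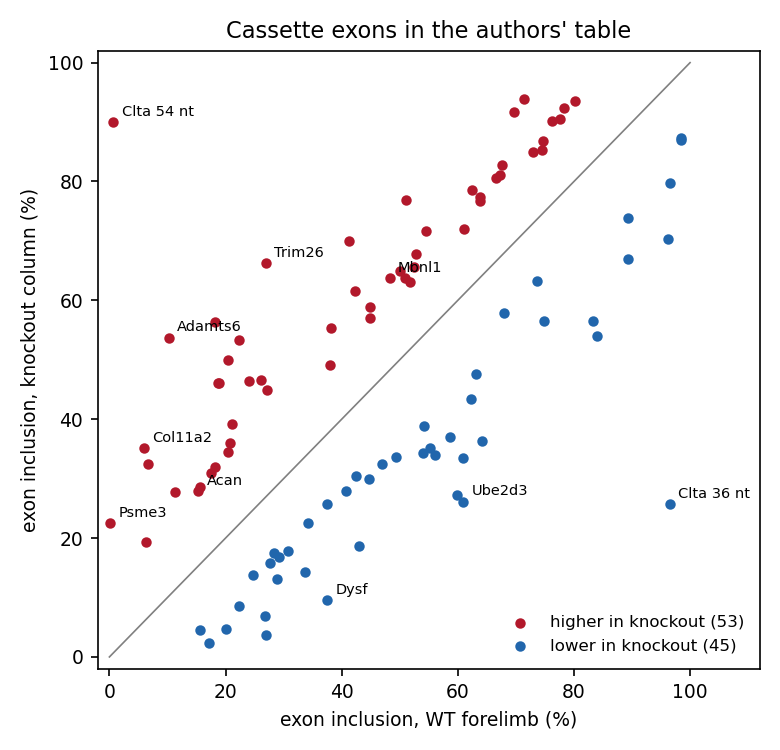
Exon inclusion in percent in WT forelimb (x axis) and in the knockout column (y axis) for the 98 events of the authors' deposited table, with 53 higher in the knockout in red and 45 lower in blue. The diagonal marks equal inclusion; the Clta exons of 54 and 36 nt lie farthest from it.

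CLIP tags were counted over the deposited span of each listed event, on its strand, and scaled to 1000000 tags of the library. They were not scaled for span length, so the values do not rank the events by density of tags. The spans were 94500 nt for Mbnl1, 2754 nt for Fgfr2, 12005 nt for the wider Rbm9 event and 5369 nt for Col2a1. Mbnl1, itself a muscleblind protein, carried 235 ± 12.7 CPM in WT (SD, n = 3), 188 ± 35.0 in ΔE2 (SD, n = 2) and 494 in C2C12. Fgfr2, a growth factor receptor, carried 132 ± 45.5 in WT (SD, n = 3) and 257 ± 111 in ΔE2 (SD, n = 2), and no tag in C2C12. Over the wider Rbm9 event the values were 91.9 ± 6.31 in WT (SD, n = 3) and 90.4 ± 22.8 in ΔE2 (SD, n = 2), with 155 in C2C12. Over Col2a1 they were 79.8 ± 20.4 in WT (SD, n = 3) and 30.1 ± 0.495 in ΔE2 (SD, n = 2), with 1.82 in C2C12. The Col2a1 values came from 2, 7 and 11 tags in WT, 2 in each ΔE2 library and 1 in C2C12. The ΔE2 SD there reflects scaling alone. These differences between genotypes were not tested gene by gene. Tags in forelimb libraries touched the events of 63 of 84 genes. A reproducible WT cluster of at least 10 tags lay within the events of 1 gene, Fgfr2, and at 5 tags within those of Arhgef12, Clta, Fgfr2, Mbnl1 and Rbm9, which makes 5 genes. At 20 tags, and without WT replicate 2 or WT replicate 3, the count was 0 of 84. The table held no unchanged exons as a background, so no test of enrichment was made.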

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

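Apart from the planned fits with other scalings and the splits of the libraries, the tests in this part were chosen only after the results were seen, and the bounds for every test were set then. ΔE2 replicates 2 and 3, labelled as separate, shared 33916 molecules of the same position, strand and barcode, against 535 expected, which drew attention because the report's comparisons use tag counts only. These molecules held 99.9% and 99.8% of the reads of the libraries. The correlation of log reads per shared molecule was 0.977 (across molecules), while it lay between -0.297 and -0.0313 in the other 14 pairs of libraries. Carry-over between lanes would leave a low copy in one library, but the lower copy had 1 read in 20.8% of shared molecules, against 63.9% to 81.4% in the other pairs. The same library sequenced more than once is thus a likely source. No biological explanation was tested.

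Molecules were also shared between libraries of different genotypes, 20258 of them between WT replicate 3 and ΔE2 replicate 1. Chance meeting of barcodes is argued against by the lowest fold over the expected number, 6.03. A common pool of material before amplification was predicted to give positively correlated reads per shared molecule. The correlation was at most -0.0600 among the 10 pairs of 5 libraries. Parts of a pool amplified separately need not correlate in reads, so this test could not decide. Carry-over of amplified molecules stays open: molecules of at least 100 reads were shared more often than those of 2 to 10 reads in at least 1 library of 9 of the 10 pairs, but in both libraries of only 7. No biological explanation was tested.

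The 62 clusters that differ between the genotypes were weighed against these shared molecules and against scaling. With molecules seen in 1 library only, 43 of the 62 could be tested and 40 of them were called, so these 40 calls did not need shared molecules. Removing molecules common to both genotypes widens their differences by construction. It took 34.3% to 45.8% of the tags of the WT libraries, 38.4% of ΔE2 replicate 1 and 10.4% of the merged ΔE2 library. The test therefore could not decide what part carry-over had. Leaving out TMM moves every called cluster down by about 0.39 on the log2 scale, so it tests the gains only: 28 of 44 were called again, which argues against scaling as their whole cause, while the other 16 kept their sign but went from a median log2 fold of 1.11 (SD 0.20) to 0.72 (SD 0.20) and stay open. The losses were tested with the size factors of DESeq2, which move them towards 0, and 13 of 18 were called again (median log2 fold -1.70 against -1.76), so a part played by scaling stays open there too. The 10 splits of the 5 libraries are too few for a share under 0.05; the real split, the 1 with as many calls, gave 62 and the highest other split 0.

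In data outside the comparisons, 86 tags lay on the Y chromosome in the forelimb libraries, although the forelimb samples are labelled as female, and 34.9% of them fell in a single bin. They came from 64 molecules, 19 of them in several of the 6 libraries. Sets of C2C12 tags marked with different colours, which no label explains, shared 68865 molecules between the larger pair, against 240 expected.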

How the results depend on the processing

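Alternatives beyond the planned ones, chosen after seeing the data, were the 6 libraries as labelled with and without a block, WT replicates 2 and 3 as 1, the treatments of shared molecules and single reads, DESeq2 on filtered clusters, and leaving out replicates for overlaps and events. Of 21 other fits of the clusters, 14 gave a count within 1.5 times 62. The others gave 7 (DESeq2), 19 (no low-count filter), 41 (5′ ends), 35 (DESeq2 on filtered clusters) and 0 (edgeR, WT replicates 2 and 3 as 1; 72 with p under 0.05). Leaving out a replicate gave 16 (WT replicate 2) to 90 (WT replicate 1); the 63 without ΔE2 replicate 1 rest on 1 ΔE2 library, assumed to vary like WT. With the 6 libraries as labelled, 85 clusters were called, and 64 with a replicate block. Deviations from the group mean correlated at -0.16, -0.04 and -0.13 between same-numbered libraries. This cannot decide whether the numbers pair them, since deviations within a group sum to 0 and ΔE2 replicates 2 and 3 share most molecules. For the 20 named clusters, 269 of 356 values under alternatives were called again, 87 missed the threshold and 0 changed sign; 13 log2 folds moved by over 1.5 times, among them 5.37 for chromosome X with tags of at least 2 reads, 1.5 for chromosome 19 at 5798304 and 1.39 for chromosome 12 without the filter, and -3.74 for the plus strand of chromosome 9 with unshared molecules.

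The 39 values of tag shares kept their direction, with the plus-strand difference at 0.626 by position and the X difference at 0.0941 without WT replicate 1. The share of WT clusters in ΔE2 was 29.0% at 20 tags, 46.8% with sets thinned, 32.0% with 6 libraries and 31% with unshared molecules, and 10.7% to 50.6% without a replicate. WT clusters in C2C12 gave 31.3% at 20 tags, 10.7% thinned, 43.0% with unshared molecules, and 35.3% to 44.9% without a replicate. ΔE2 clusters in C2C12 gave 12.7% thinned and 41.5% to 49.5% without a replicate. The events numbered 32 at a change of at least 0.2. Genes with a cluster in an event numbered 5 at 5 tags and 0 at 20 tags, and 0 to 1 without a replicate. Thinning uses fewer tags and stricter minimums fewer clusters by construction; for the rest the cause was not tested. Not run, for lack of mm9 annotation, were the alternatives for tests per gene, gene lists and the YGCY motif. Depth limits all cluster results, since 116076 of 191766 clusters hold 1 tag.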

Other observations

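The tests in this part were chosen after the results were seen. Of the 44 clusters higher in ΔE2, 29 overlapped a C2C12 cluster (65.9%), and of the 18 lower in ΔE2, 10 did (55.6%), beside 111 of the 214 clusters that were not called (51.9%). The hypothesis that sites lower in ΔE2 are those also bound in myoblasts was left open by Fisher's exact test of lower against higher clusters (two-sided p = 0.564). C2C12 cells had 308 tags in the 5 clusters that rose in ΔE2 at the minus-strand locus of chromosome 19, and 341 in the 4 that rose at the chromosome 17 locus.

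Cartilage genes in the authors' deposited table moved towards inclusion in 3 of 3 cases, and 44 of the other 81 genes had an exon that did so (54.3%). Fisher's exact test gave a two-sided p of 0.252, the smallest that 3 genes allow in this direction, so the test could not decide whether cartilage genes move this way more often than others. With overlapping forms of an exon in the authors' deposited table counted once, by the form with most inclusion tags, those with higher inclusion in the knockout had a length that is a multiple of 3 in 30 of 47 cases (63.8%) and those with lower inclusion in 23 of 40 (57.5%). The difference in reading frame gave a two-sided Fisher p of 0.660, with a 95% interval from -13.7 to 25.9 percentage points, so it was not settled at this number of exons. In 3 genes, Clta, Rbm9 and Macf1, the authors' deposited table held exons of both directions, which in Clta and Rbm9 share a junction and its tags.

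Ranks in the authors' deposited table ran from 2 to 187, and 88 ranks in that range are not among the events analysed here.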
